A study of Mus musculus with 2 samples.

How the data were processed

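Chromatin contacts of the mouse immunoglobulin heavy chain locus (Igh, chromosome 12) were measured by 5C, which crosslinks chromatin, cuts it with HindIII, ligates fragments that lie close together and amplifies ligation products with forward and reverse primers placed on fragment ends. Each forward primer pairs with each reverse primer, so a pair of fragments carries 1 value. Both libraries came from C57BL/6 splenic B cells depleted of CD43-positive cells and cultured for 40 hours with LPS and IL4. They form 1 group of 2 replicates, which the series description calls biological replicates, so no comparison between conditions was possible.

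The deposited tables hold counts, whole numbers of sequenced products per primer pair, and the per-replicate totals differ. Per the submitters' processing notes, Novoalign and the mouse build mm9 were used, with no version given in the sources used here. Per the file headers, the matrices passed through a step named transpurge, and fragment positions are in mm9. Both tables hold the same 98 forward and 108 reverse Igh fragments, which make 10584 pairs over 206 fragments. Gene desert pairs on another chromosome, which the series description names as a control region, were not analysed here. The planned comparison of Igh with the gene desert and the expected counts taken from it were therefore not run.

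No mm9 gene annotation or genome was used here, and the gene table at hand is on another assembly, GRCm38.p6. Coordinates were not converted. No fragment was assigned to a gene, the planned list of landmark pairs was not run, and fragments are given by number and mm9 position. As fixed for that case, the probed span was divided into 5 parts of equal length (602 kb).

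Distances were taken between fragment midpoints. For each replicate, a lowess curve (span 0.3) of counts on log10 distance gave the expected count, and another of squared residuals gave the SD, over the 10415 pairs at least 10 kb apart. The residual over the SD gave z, a Weibull distribution fitted to shifted z gave an upper-tail p, and Benjamini-Hochberg adjustment gave q. A pair was called when q was under 0.01 in both replicates. Overlaps were set against 100000 one-sided random placements within 10 distance bins, and the correlations against 100000 permutations within those bins. A pseudocount of 1 was used for log2 counts. Differences between parts were tested with two-sided circular-shift permutations of the fragment order. Only 206 distinct shifts exist, fewer than planned, so the smallest p is 0.00485. Insulation of a fragment is the log2 mean observed over expected ratio of pairs that span it within 250 kb on both sides.

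Counts were also corrected for primer coverage, by dividing observed over expected ratios in 50 rounds by the mean ratio of each forward and each reverse primer. For the neighbours of called pairs, in the closing section, and for ratios marked so in the Results, the primer means and the expected curve were fitted without called pairs. That choice was made after the data were seen. The primer correction, other spans, thresholds, nulls, scales, distance minimums, windows and detection levels, and each replicate alone, were chosen before the data were examined. The exact form of the correction, the floors of the curves and the definition of an insulation minimum (the lowest of a fragment and its 5 neighbours on each side) were set after the tables had been opened and provisional calls run. The fragments and pairs named are the 20 called pairs with the highest mean z, the 5 fragments with the most called partners and the 3 deepest insulation minima, by a rule fixed before the data were examined; ties at 2 partners were ordered by mean ratio. Further pairs were chosen after their values were seen, as stated where they appear.

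The procedures were tested on simulated data with the measured distance trend, primer factors and replicate noise. The trend and factors were measured over pairs at least 10 kb apart, called pairs included. Over 10415 pairs, with 50 pairs raised at each size, the calling of counts recovered 8 pairs raised 100-fold, 1 raised 50-fold, 0 raised 20-fold and 1 raised 5-fold, and called 10 of 10215 unraised pairs. With primer correction it recovered 47, 36, 9 and 0 and called 0 unraised pairs. Without simulated primer differences, counts gave 49, 41, 3 and 0, also with 0 unraised pairs. Of 15 part combinations raised 5-fold in turn, the shift test of counts recovered 0, and the test of corrected counts recovered 14 with 29 calls of other combinations. Of 10 insulation sites lowered 5-fold, 6 were found in counts and 10 in corrected counts. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

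Totals of 14503618 and 17658603 counts give narrow counting intervals for shares of all counts. The median pair held 41 counts in replicate 1 (95% exact Poisson interval 29.4 to 55.6) and 73 in replicate 2 (57.2 to 91.8). Intervals cover counting error only, since no molecular identifiers are named in the sources used here.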

Results

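The map covered chr12:114339456-117350186 (mm9), a span of 3.01 Mb that holds the Igh locus, in splenic B cells activated with LPS and IL4, a treatment that induces switching to IgG1 and IgE. The 206 probed HindIII fragments had a median length of 2803 bp and covered 25.97% of the span, and the longest unprobed gap was 165 kb. The question set by the series was which fragments of the locus contact each other in both replicates. In the GRCm38.p6 gene table the order along the chromosome is Tmem121, the constant genes from Igha to Ighm, the J and D segments and then the V segments. The 3' regulatory region, a cluster of enhancers, lies beyond Igha, and the Eμ enhancer lies between the J segments and Ighm. No fragment was placed on these elements, because no mm9 annotation was used here.

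Contacts were recorded across the whole locus. Of the 10584 pairs, 10236 in replicate 1 and 10564 in replicate 2 had a count above 0, and 10221 (96.6%) did in both. Random placement within distance bins gave a mean overlap of 10216.9 pairs (one-sided permutation p = 0.00183), an excess of few pairs because nearly all pairs were detected. Detection alone therefore separated few contacts from the rest. Short distances took most of the sequencing: 81 pairs of adjacent fragments held 63.7% of the counts in replicate 1 (95% Wilson interval 63.7 to 63.8) and 53.9% in replicate 2 (53.9 to 53.9). The 5131 pairs at least 1 Mb apart held 2.43% and 2.58%.

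The 2 replicates ranked the contacts similarly. Across pairs, log2 counts had a Pearson r of 0.844 and a Spearman rho of 0.796, and after removal of the distance trend r was 0.763 and rho 0.762. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give, and pairs of 1 locus are not independent replicates. After correction for primer coverage, rho without the distance trend was 0.537. Single fragments differed between replicates in several parts of the locus. The share of all counts was higher in replicate 2 by 16.3 times for forward fragment 702 (chr12:116864979-116868374), 14.1 times for reverse fragment 552 (chr12:116364360-116366864), or 8.47 and 5.48 times without the pair that joins these fragments, 12.2 times for reverse fragment 428 (chr12:115848051-115855284) and 7.69 times for forward fragment 23 (chr12:114441222-114447060). Shares of all counts include pairs of adjacent fragments. Over pairs at least 10 kb apart, reverse 428 had mean observed over expected ratios of 0.173 in replicate 1 and 0.409 in replicate 2. Forward 23 had 0.131 and 0.422. These fragments were picked after their values were seen.

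Counts fell with distance up to about 1 Mb. The slope of log10 mean count on log10 distance was -1.20 ± 0.0083 (SD, n = 2) over all distances, and between 10 and 500 kb it was -1.23 in replicate 1 and -1.03 in replicate 2 (SD 0.141). In replicate 1 the mean count was 525.8 between 119 and 274 kb, 119.6 between 274 and 487 kb, 88.02 between 487 and 736 kb and 60.3 between 736 and 967 kb. Replicate 2 gave 738.5, 245.1, 334.3 and 89.4, so its mean did not fall at each step. Its median count did, from 208.5 in the first of these bins to 52 in the last. The 1059 pairs between 487 and 736 kb include forward 556 with reverse 705, with 156364 counts in replicate 2. They also include forward 702 with reverse 552, with 37357. These pairs raise the mean of that bin, so its rise does not show a rise of typical counts. Beyond 1 Mb counts not corrected for primers stopped falling, with a slope of 0.28 ± 0.15 (SD, n = 2), and the farthest bin, 2281 to 3006 kb, averaged 92.3 and 100.9 counts. With terms for each primer, mean log2 levels were lower in the bin before the farthest than near 1 Mb, as given in the closing section.

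**Figure D1:**
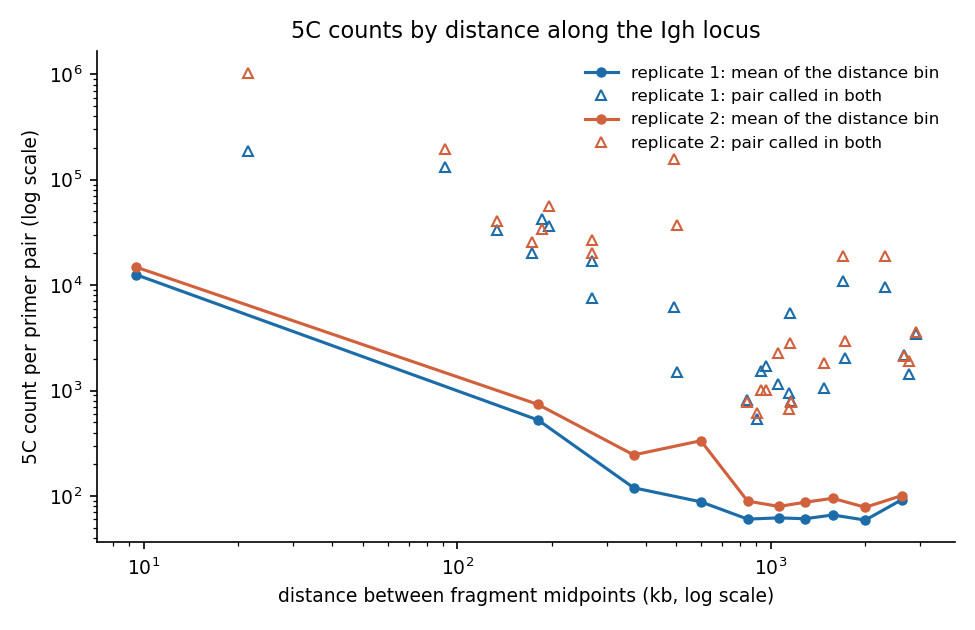
Mean 5C count of each of 10 distance bins (lines) for both replicates, drawn at the geometric mean of the bin's limits, with the 25 pairs called in both replicates as triangles, on log axes. The called pairs lie above the mean of their distance, and the bin means, not corrected for primers, stop falling near 1 Mb.

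A small number of pairs had counts far above the level of their distance in both replicates. Of 10415 pairs tested, 45 were called in replicate 1, 39 in replicate 2 and 25 in both, with mean observed over expected ratios from 8.12 to 280. Of the 25 pairs, 18 (72%) had a fragment in part 1 (chr12:114339456-114941601), 13 (52%) joined part 1 to another part and 11 (44%) spanned over 1 Mb. Among all tested pairs, 57.97% had a fragment in part 1, 46.3% joined part 1 to another part and 49.3% spanned over 1 Mb, and these shares were not tested against each other. Random placement within distance bins gave a mean of 0.194 shared pairs and at most 4 (permutation p = 1e-05, the smallest possible). That placement ignores primers, and simulated libraries with the measured primer factors but no pair raised gave a mean of 7.25 shared calls, from 2 to 16. Calling on counts corrected for primer coverage gave 33 pairs, of which 14 were among the 25, and its simulation without raised pairs gave a mean of 0.02. Both simulations drew noise separately in each replicate and held no effect of a single primer pair that both replicates share. Their primer factors and expected curve were measured with called pairs included, so signal of called pairs was spread over other pairs of the same primers. The means of the simulations are therefore not rates of false calls, nor the yield of primer differences alone.

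Several called pairs stayed called after primer correction, with other ratios. A pair counts in its own primer means, which limits its corrected ratio, so a small SD of corrected ratios does not show close replicates. Forward fragment 517 (chr12:116222484-116231679) and reverse fragment 41 (chr12:114528706-114531105), 1697 kb apart, shared 11058 and 19017 counts, a ratio of 191 ± 26.5 (SD, n = 2) to the expected count and 38.5 ± 2.00 after correction. Forward fragment 165 (chr12:114973711-114977500) and reverse fragment 819 (chr12:117289594-117292548), 2315 kb apart, had a ratio of 163 ± 57.9, and 63.2 ± 1.69 after correction. In part 5, forward fragment 792 (chr12:117189453-117190694) and reverse fragment 768 (chr12:117095670-117102068) had a ratio of 119.7 ± 7.86, and 26.1 ± 10.2 after correction. Forward fragment 685 (chr12:116809861-116811073) in part 5 and reverse fragment 606 (chr12:116539430-116542358) in part 4 had 52.1 ± 1.66, and 43.8 ± 10.4 after correction. The widest separation was that of forward fragment 18 (chr12:114404465-114408145) and reverse fragment 831 (chr12:117305833-117307899), 2901 kb apart, with 3475 and 3562 counts and a ratio of 35.4 ± 2.75, or 17.1 ± 3.58 after correction. Forward 36 with reverse 810 was among the 25 pairs too but outside the 20 named by rule, and was picked after its values were seen, with a ratio of 17.4 ± 4.15 at 2768 kb, or 20.9 ± 2.02 after correction. Forward 842 (chr12:117325410-117328516) with reverse 83 (chr12:114667887-114670119), 2658 kb apart, had 22.9 ± 0.57, or 12.1 ± 4.12 after correction.

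Further calls lay between 21.5 and 1140 kb. Forward fragment 28 (chr12:114465909-114474052) and reverse fragment 24 (chr12:114447061-114449887), 21.5 kb apart, held 186765 and 1027548 counts, and forward 115 (chr12:114778143-114787052) with reverse 70 (chr12:114647312-114649351), 134 kb apart, had a ratio of 41.1 ± 5.57. Forward 624 (chr12:116605743-116610576) with reverse 705 (chr12:116875021-116877871), 268 kb apart, had 30.7 ± 10.6, and forward 40 (chr12:114522182-114528705) with reverse 274 (chr12:115364817-115370798), 842 kb apart, had 10.97 ± 3.82. All of these were also called after primer correction. Forward 329 (chr12:115586578-115589686) with reverse 41, at 23.1 ± 5.93 and 1058 kb, and forward 346 (chr12:115628291-115630212) with reverse 33 (chr12:114486613-114491122), at 11.6 ± 5.06 and 1140 kb, were not. Under other settings, forward 624 with reverse 705, forward 40 with reverse 274 and forward 346 with reverse 33 lost their call at q under 0.001 and at a lowess span of 0.6, and forward 28 with reverse 24 lost it without a minimum distance. Forward 702 with reverse 552 lost it at spans of 0.1 and 0.6, and forward 346 with reverse 33 also at 0.1. Among pairs of reverse 81, those with forward 334 and forward 346 lost it at 0.6, and that with forward 556 at 0.1. Of the 20 pairs named by rule, 17 stayed called at q under 0.001, 17 at a span of 0.1, 14 at a span of 0.6 and 0 on the log2 scale. For 3 of the 25 pairs the replicates differed over 4-fold in share of counts, and the difference was as large as the value itself for forward 556 (chr12:116385510-116386658) with reverse 705, at ratios of 61.5 and 499, and for forward 702 with reverse 552, at 15.1 and 120. After primer correction these pairs had 31.1 and 39.5, and 61.9 and 97.9. The primer means used for the correction include the pair itself, which limits the corrected ratio: in replicate 2, forward 702 with reverse 552 held 81.9% of the counts of its forward fragment and 83.3% of those of its reverse fragment, so closer corrected values do not show closer replicates. The pair of forward 28 and reverse 24 was the other, at 49.03 and 134, and 53.1 and 39.7 after correction.

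**Figure D2:**
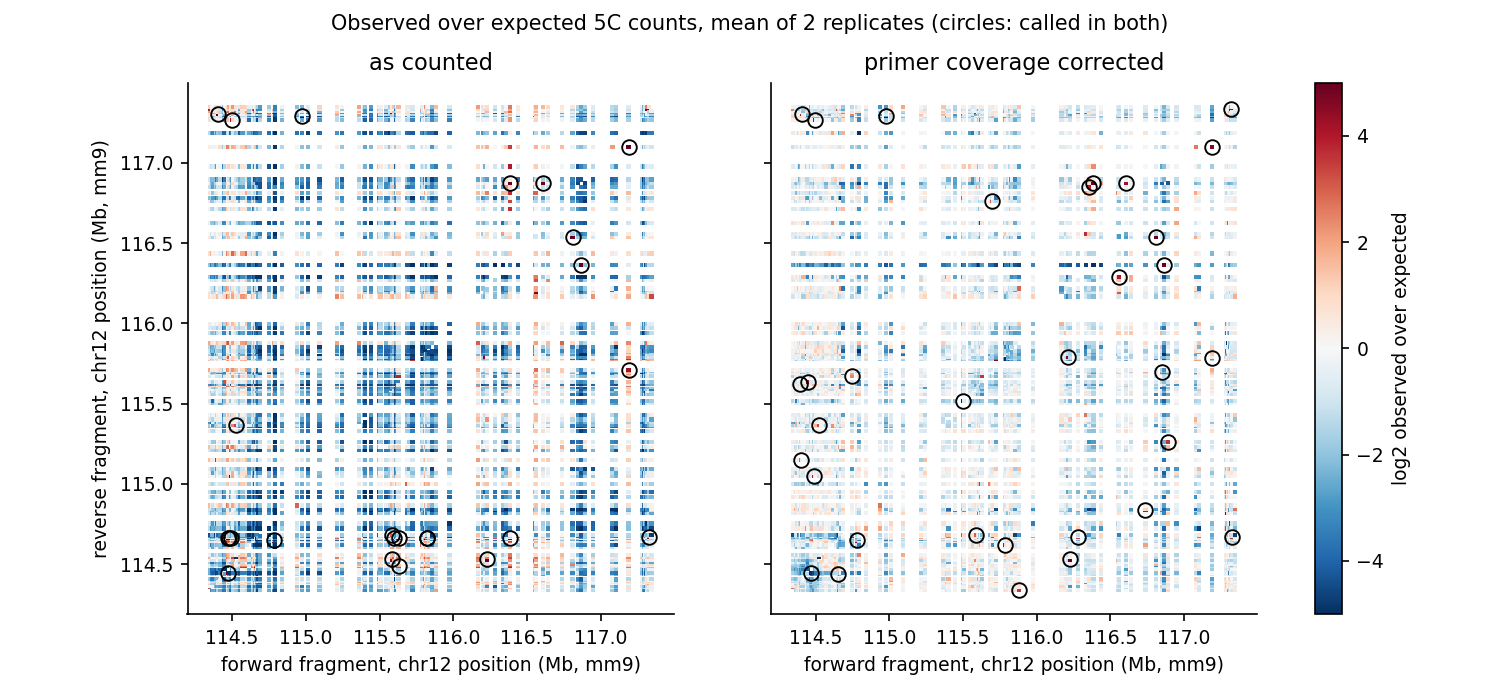
Log2 observed over expected 5C counts, mean of 2 replicates, for the 10415 pairs at least 10 kb apart, by mm9 position of the forward (horizontal axis, Mb) and reverse (vertical axis, Mb) fragment, as counted (left) and after primer correction (right). Circles mark the 25 and 33 pairs called in both replicates, values beyond the colour scale take its end colours, and the stripes of whole fragments in the left panel are weaker in the right one.

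Reverse fragment 81 (chr12:114664824-114667095) held 8 of the 25 called pairs, and no other fragment held over 2. Its called partners formed groups along the locus. Forward 28 at 196 kb, forward 31 (chr12:114477117-114480873) at 187 kb and forward 34 (chr12:114491123-114493851) at 173 kb had ratios of 76.5 ± 4.06, 62.1 ± 25.2 and 32.5 ± 2.91. Forward 334 (chr12:115594002-115605173) and forward 346 had 19.1 ± 10.1 and 20.5 ± 11.9, forward 415 (chr12:115816276-115822016) and forward 419 (chr12:115824507-115826299) 60.4 ± 37.3 and 10.95 ± 2.43, and forward 556 32.1 ± 1.05 at 1720 kb. Its pairs with forward 34 and forward 419 fell outside the rule and were picked after their values were seen. The mean ratio of fragment 81 was 5.83 ± 1.88 over its 93 pairs and 2.68 ± 1.06 (SD, n = 2) over the 85 that were not called, and after primer correction 0 of its pairs were called in both replicates. This 0 does not show that the contacts were absent. The called pairs made up 56.2% and 60.8% of the summed ratios of fragment 81, so they raised the primer mean that they were divided by. In simulation, corrected calling also recovered 0 of 50 pairs raised 5-fold and 9 of 50 raised 20-fold. At an unadjusted p under 0.05 from the Weibull fit, without permutation, 4 of its 93 corrected pairs passed in both, against 125 of all 10415 corrected pairs.

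After correction, the near group and forward 415 kept the highest ratios among the called partners. Forward 28 had corrected ratios of 4.09 and 4.75 with reverse 81, forward 31 had 5.47 and 6.92, and forward 34 had 6.31 and 6.73. The next fragment, forward 36 (chr12:114496829-114501530), had 1.14 and 0.91, and forward 25 (chr12:114449888-114450784) on the other side had 0.62 and 0.35. Forward 415 kept 5.67 and 5.18, and forward 556 had 2.15 and 1.55. These ratios are lowered by the called pairs' own share of the primer means. With primer means taken without called pairs, forward 28 had 9.10 and 9.81, forward 31 7.07 and 10.3, and forward 34 8.31 and 9.71. Forward 415 then had 7.10 and 7.57, and forward 556 4.12 and 2.82. The other fragments named by number of partners held 2 each: forward 556, forward 28, reverse 705 and reverse 41, all with a partner called after correction.

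**Figure D3:**
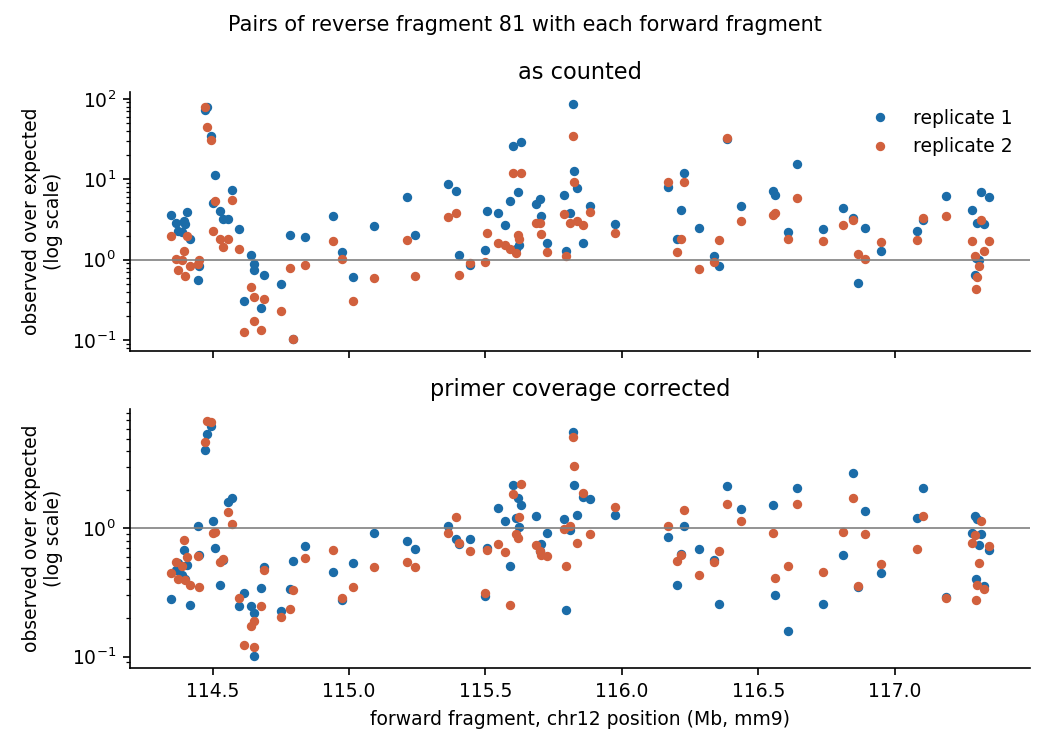
Observed over expected 5C count (log axis) of reverse fragment 81 with each forward fragment, by mm9 position of the forward fragment (Mb), for both replicates, as counted (top) and after primer correction (bottom). The line marks a ratio of 1, and the called fragments 28, 31 and 34 lie between 30.5 and 79.9 as counted and between 4.09 and 6.92 after correction.

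Mean ratios varied between the 5 parts, and the replicates differed in some of them. Parts 4 and 5 (chr12:116145895-117350186) had a mean ratio with each other of 1.35 in replicate 1 and 2.96 in replicate 2, and without forward 556 with reverse 705, left out after the values were seen, of 1.21 and 1.84. Parts 1 and 4 had 1.39 and 1.37, and pairs within part 3 (chr12:115543748-116145894) the lowest, 0.287 ± 0.034 (SD, n = 2). After primer correction parts 4 and 5 had 1.32 ± 0.04, parts 1 and 4 had 0.940 ± 0.0047 and part 3 had 0.626 ± 0.035. Median ratios of counts were below 1 for all 15 combinations, with 0.594 for parts 1 and 4 and 0.554 for parts 4 and 5. Of the 15 combinations 0 were called in both replicates by circular-shift permutation, with a lowest adjusted p of 0.146, and 0 were below 0.05 unadjusted in both. With 206 shifts and 15 combinations, 1 combination alone cannot have an adjusted permutation p below 0.0728. In simulation, the test of counts recovered 0 of 15 combinations raised 5-fold, so its lack of calls says little. The corrected test recovered 14, with 29 calls of other combinations. Its lack of calls speaks only to differences of about that size and does not show that the parts were alike.

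Insulation scores were low across much of part 3, which held the 3 deepest minima shared by both replicates. The insulation score, available for 148 fragments, correlated between replicates across fragments (rho 0.870). Scores of neighbouring fragments share pairs, so the 148 values are not independent. They were not corrected for primers, whose factors also correlated between replicates (rho 0.803 for forward and 0.862 for reverse primers). The scores had 5 minima shared by both replicates. Of these, forward 611 (chr12:116559256-116561326) was low in replicate 1 alone (log2 ratios of -0.43 and 1.26). The deepest lay at forward fragment 436 (chr12:115880011-115885590), where the log2 ratio was -2.72 ± 0.85 (SD, n = 2), then at reverse fragment 339 (chr12:115616163-115618624) with -2.08 ± 0.05 and reverse fragment 374 (chr12:115706727-115709849) with -1.98 ± 0.13. Within 250 kb above forward 436 only reverse 450, reverse 457, forward 458 and reverse 464 were probed. Their primer factors were 0.115 to 0.498 in replicate 1 and 0.330 to 1.31 in replicate 2. The other 2 minima differed little from nearby fragments: forward 340, near reverse 339, had -1.97 and -1.94, and forward 371, near reverse 374, had -1.97 and -1.76. After primer correction the ratios at these fragments were -1.07 and -0.94, -0.60 and -0.56, and -0.69 and -0.62, and reverse 339 was no longer a minimum. With windows of 100 and 500 kb the replicates shared 2 and 1 minima, after primer correction 7, and no test was made of depth or position.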

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

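Calling after primer correction combined with the log2 scale, thinning replicate 2 to the depth of replicate 1, the limit on differences between replicates, the removal of reverse fragment 81 or of forward 556 with reverse 705, and the median of ratios were chosen after the data were seen. The number of pairs called in both replicates stayed between 19 and 33 under every alternative with both replicates but 1: on the log2 scale it was 0 (0 in replicate 1 and 22 in replicate 2, and 252 pairs at an unadjusted p under 0.05 in both, by the same Weibull fit without permutation). Primer correction with the log2 scale gave 25 pairs, 11 of them among the main 25, and primer correction alone shared 14. Without one replicate, 39 to 45 pairs were called, since no overlap was then asked for. The decay slope was -1.19 over pairs above 0 and -1.13 between 10 and 500 kb. Reverse fragment 81 had 0 called partners after primer correction. Insulation minima numbered 2 with the 100 kb window and 1 with the 500 kb window. The causes were not tested, except that a single replicate drops the overlap. The detected pairs and the correlations kept their side under their alternatives. Part combinations gave 0 calls under each, in a test where 1 combination alone cannot pass. The corrected test could still call in simulation, where it recovered 14 of 15 combinations raised 5-fold, with 29 other calls. The gene desert comparison, its use as background and the landmark pairs were not run with any alternative. Counts of 10 or fewer in 2457 pairs of replicate 1 and 632 of replicate 2 limit what could be seen at long distance.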

Other observations

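The tests of the block of contacts and of the single pairs were chosen after their results were seen. The test of the farthest distances against intermediate ones was written down before its fit was run, but after the rise itself had been seen, and the test against the bin before was chosen after that fit. The test of neighbours was changed more than once after earlier forms had been run, last to take primer means without called pairs, because a called pair raises the means of its primers and so lowers the corrected ratios of its neighbours.

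Fragments 28 to 35 (chr12:114465909-114496828) and 76 to 81 (chr12:114656273-114667095) had corrected ratios above 1 for all 18 pairs that joined them, in both replicates. The 9 pairs with forward fragments of the first interval had medians of 5.78 and 6.13, and the 9 with the roles exchanged, which share no primer with these, had 2.94 and 4.17, a level that 8 and 7 of 473 blocks of that shape at a similar distance reached, the block itself and overlapping ones included. The ratio of 2.94 without the primer of reverse fragment 81 argues against high amplification of that primer as the whole cause. All other pairs of part 1 at the distances of the block had medians of 0.797 and 0.769 and an upper quartile of at most 1.38, which argues against general compaction of this end to the level of the block. A contact between the intervals is a candidate explanation, as a hypothesis from the same data, and with 1 condition no biological explanation was tested.

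Most called pairs outside this block had nearest pairs at under 2 times the expected level. Over the 21 such pairs with a nearest probed pair within 30 kb, and with primer means taken without called pairs, the median corrected ratio of the nearest pairs had a median of 1.06 and 1.19 and an upper quartile of at most 1.81. For most of the 21, these values argue against contacts that raise the nearest pairs to 2 times the expected level. A smaller rise cannot be excluded, because the expected level is a mean and typical corrected ratios lie below it. At the distances of the block, with called pairs kept in the primer means, medians were 0.797 and 0.769 for other pairs of part 1. Elsewhere they were 0.561 and 0.612. The 3 called pairs of the block had 3.81 or more. Their nearest pairs include other pairs of the block, which was picked for its high ratios, so they are no independent comparison. The exceptions, at 2 or more in both replicates, were forward 419 with reverse 81 (2.64 and 2.21), forward 702 with reverse 552 (4.39 and 5.73) and forward 792 with reverse 374 (3.24 and 3.52), and 7 of the 21 had fewer than 3 nearest pairs. For forward 419 with reverse 81, the nearest pairs include the called pair of forward 415 with reverse 81 (7.10 and 7.57). Against all pairs within 30 kb, the 24 called pairs with such neighbours had a median excess of 11.3 times in the lower replicate, and 12 exceeded 10 times in both and 2 stayed under 2 times in both, forward 346 with reverse 33 (0.72 and 1.29) and forward 792 with reverse 374 (1.54 and 1.67). For the pairs with a large excess, amplification or mis-annealing particular to a primer pair could be the source, and so could a contact of a single fragment; without primer sequences these cannot be told apart.

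Counts of the farthest bin were higher than at intermediate distances. On the log2 scale, this bin lay 0.58 and 0.11 above the mean of the bins between 967 and 1755 kb, and with terms for each forward and reverse primer it lay at -0.13 and -0.12. Primers at both ends that amplify more than others could therefore account for the excess over those bins (mean of -0.125 with primer terms). Over the bin before it, the farthest bin rose by 0.65 and 0.20 without primer terms and by 0.21 and 0.19 with them (mean 0.199), so most of this step went with primers in replicate 1 and little of it in replicate 2, which leaves its cause open. With primer terms, levels also fell from the bin of 1166 to 1417 kb to that of 1758 to 2281 kb. They went from 0.10 to -0.34 in replicate 1 and from 0.12 to -0.31 in replicate 2. Without these terms they went from 0.10 to -0.07 and from 0.16 to -0.09. The bin of 967 to 1166 kb had 0.07 and 0.11 with primer terms, slightly under the bin after it, so the fall was not steady. Levels of the bin of 1758 to 2281 kb were thus lower than those near 1 Mb, by more once primers were in the fit. The slope of 0.28 beyond 1 Mb was taken on mean counts and not on log2 counts, so it is no direct comparison. The design gives no biological explanation to test.

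The 8 called pairs of reverse 81 were slightly more than any fragment had in simulations of primer differences. In 100 simulated libraries with the measured primer factors and no pair raised, the fragment with the most shared calls had 3.55 on average and at most 7. Those factors were measured with called pairs included, which made up 56.2% and 60.8% of the summed ratios of fragment 81. The simulated level of fragment 81 thus holds signal of the pairs under test. For that reason the comparison cannot decide whether primer differences alone give 8 calls. Effects of single primer pairs that both replicates share were not simulated, so the comparison cannot exclude them. The margin also depends on settings: the pairs with forward 334 and forward 346 lost their call at a lowess span of 0.6, and that with forward 556 at 0.1. Corrected calling added 19 pairs not among the 25. Forward 306 with reverse 312, 20.4 kb apart, had corrected ratios of 67.8 and 55.2. Forward 513 with reverse 403, 425 kb apart, had 22.9 and 26.2. Some others held few counts. Forward 694 with reverse 368 had 25 and 151 counts, ratios of 0.398 and 1.801 as counted and 7.76 and 7.19 after correction. Its primer factors were low, 0.209 and 0.527 for forward 694 and 0.217 and 0.375 for reverse 368. Forward 14 with reverse 342 had 133 and 91 counts, ratios of 2.13 and 1.08 as counted and 7.94 and 5.83 after correction. The call of such pairs depends on the factors they are divided by. The pairs named here were picked after their values were seen.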
